A study of Mus musculus with 6 samples.

How the data were processed

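The 6 samples were coronal sections of wild-type C57BL/6J mouse brain, 2 each from postnatal days 6, 12 and 60 (P6, P12 and P60). C57BL/6J is a common inbred laboratory strain. Each section was placed on a Visium slide, whose surface carries a grid of barcoded capture spots that bind polyadenylated RNA from the tissue above them. A spot is a small area that can hold several cells of different types, so no value below is a value of a single cell. The labels do not say whether the 2 sections of an age came from different animals. P-values of single genes and of the association across spots therefore measure only the spread between these sections, which may be technical. The order of the sections of P6 and P12 in the repository gave their replicate numbers, called first and second here.

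The deposited matrices hold raw UMI counts per gene and spot (unique molecular identifiers, which count captured molecules rather than reads), as whole numbers and without normalization, per the file headers. All matrices share the same 32285 genes, paired with symbols in the deposited feature tables. Per the submitters' processing notes the counts were made with Space Ranger against the mouse build mm10, and Seurat is also named there without a version. The notes give Space Ranger 3.1.0 for the first sections of P6 and P12 and 1.3.1 for the other 4 sections. The matrix headers of those 2 first sections name spaceranger-1.3.1, and the headers of the other 4 matrices name no software. The notes and headers therefore disagree on the version, and the version is used below only as a name for the 2 sets of sections. P60 is present only in the set of 4. Section images and spot positions were not used here. Gene positions were taken from an annotation of GRCm38.p6, the assembly that mm10 names, and 96.1% of the 16331 genes tested in whole sections had one.

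Total counts per section ran from 15143813 to 191100513 UMIs, and each value from a section sum has a counting precision set by these totals. All deposited spots entered the whole-section sums. No barcode list beyond the filtered spots was used, and no doublet caller was run because spots hold several cells by construction. Sections of 1 age were compared before they were averaged. A chi-square statistic of their counts over genes with at least 100 UMIs averaged 321, 539 and 82.5 per gene at P6, P12 and P60, so no pair was the same library deposited more than once.

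For each age comparison the counts were summed over all spots of a section. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 with TMM normalization, the filterByExpr low-count filter and Benjamini-Hochberg adjustment at 0.05. All 6 sections entered 1 fit with age as the only factor, called the age-only fit below, which leaves 3 residual degrees of freedom. Fits with Space Ranger version as a term, and fits on the 4 sections of the larger set alone, were also planned. The 4 sections hold 1 section each of P6 and P12 and leave 1 residual degree of freedom, from the 2 sections of P60. The tests, the gene lists, the region markers, the rule for named genes and most alternatives were fixed before the data were examined. The quasi-likelihood fits of whole sections were run once in an exploratory way before the analysis was assembled, and the design was not altered afterwards. Levels are given as CPM, counts scaled by TMM-adjusted library size, as mean ± SD of 2 sections unless said otherwise. Fold changes come from the fitted model. The median log2 fold change over all tested genes lay between -0.05 and 0.08 in the whole-section fits. The scaling places the bulk of genes near 0 by construction, so this median cannot show whether a comparison was shifted as a whole.

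A total of 34 gene lists with 532 symbols were fixed, and 528 symbols were found in the tables. The lists cover endothelium (pan-endothelial, blood-brain barrier, tip cell, arterial and venous), mural cells (pericyte and smooth muscle), basement membrane, fibroblasts and meninges, TGF-beta and BMP signalling (ligands and activation, receptors and transducers, target genes), Wnt beta-catenin signalling, VEGF with Notch and angiopoietin, and the hypoxia response. They also cover cell division, immature neurons, synapses and mature neurons, inhibitory neurons, astrocytes, radial glia, oligodendrocyte precursors, myelin, microglia, activated microglia of developing white matter, perivascular macrophages, red blood cells, choroid plexus, ependyma, cholesterol synthesis, immediate early genes, brain extracellular matrix, mitochondrially encoded genes and ribosomal proteins. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes. Camera compares the genes of a list with all other genes. A small camera p-value at the preset correlation is therefore no measure of how well the sections of an age repeat each other. With a correlation estimated from the sections no list passed in any of the 3 comparisons, so the adjusted p with an estimated correlation is given beside each list described. The estimate was not always above the preset. For P60 against P6 it was -0.0297 for cell division and -0.0271 for synapse genes. A higher correlation between genes therefore does not account for the loss of every call. Counts of list members were also made with p-values adjusted over the list alone.

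Regions were found by clustering the spots of each section separately, so that age did not enter the clustering. Spots with at least 500 UMIs were used, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2). A cluster took the name of 1 of 10 regions from its mean log2 enrichment of fixed marker genes. The enrichment it had to reach was lowered to 0.25 with a lead of 0.2 over the next region after the scores had been seen, and before any test in cortex was run. A midbrain name was withdrawn because habenula genes led the cluster. Clusters without a name held 28.0%, 20.0%, 24.5%, 16.4%, 20.0% and 15.5% of the clustered spots in the first and second sections of P6, P12 and P60. The cerebral cortex class held 448, 688, 990, 907, 912 and 660 spots in the same order. Clusters that scored highest for cortex but were kept out of the class held 381, 145, 260, 0, 287 and 341 spots, which is 46.0%, 17.4%, 20.8%, 0%, 23.9% and 34.1% of all spots that scored highest for cortex. One cortex cluster of 266 spots in the first P12 section was shallow and led by mitochondrial and ribosomal RNA genes; it was kept, and its removal was added as an alternative after seeing the data.

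Cortex spots were summed per section and tested as the whole sections were, with the marker genes of the regions left out. A region-by-age interaction was tested in edgeR on 12 sums, cortex spots and all other spots of each section, with the section as a block. The other spots include the clusters that scored highest for cortex but were kept out of the class. The genes reported from it are the members of the 14 vascular and signalling lists. For association across spots, spots were thinned to 2000 UMIs and shallower spots were left out (4, 424, 6, 574, 117 and 344 spots). Spearman's rho of each list's UMI sum with that of the pan-endothelial list was taken within each section, transformed to Fisher z and compared between ages with limma over 33 lists. The section, not the spot, was the replicate.

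Named genes follow a fixed rule. For each comparison of whole sections it takes the 6 genes per direction with the largest fold change at an adjusted p under 0.05, a mean of at least 20 CPM, sections of the 2 ages that do not overlap, and a proper symbol. It adds up to 4 members of each described list with the smallest adjusted p, any tested member of the TGF-beta lists, 5 genes per direction in cortex, 6 list genes for the interaction, and 4 lists per direction for the association. One gene that the rule takes is not reported here. Genes of a family with close paralogs, such as Tubb2b, Ly6a, Ly6c1 and the alpha globins, are uncertain because the way in which shared reads were counted is not given in the sources used here.

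The tests were checked on simulated data. In data drawn from the real means and library sizes, 200 genes were changed. Without a difference between the 2 sets of sections, the age-only fit recovered 18.0% of 2-fold, 96.0% of 4-fold and 100% of 8-fold and 16-fold changes for P60 against P6, over 16078 genes. With the difference between sets as estimated from the sections, the age-only fit recovered 0 genes at every size, and the fit with the version term recovered 14.0%, 86.0%, 100% and 100% over 16104 genes with 9 false calls. For P12 against P6 the version-term fit recovered 26.0%, 94.0%, 100% and 100% with 11 false calls, for P60 against P12 it recovered 10.0%, 92.0%, 100% and 100% with 8, and the age-only fit recovered 0 in both. The simulated difference was the same in all sections of a set, as the version-term fit assumes. The real P60 sections differed along that pattern, and false calls in that case were not simulated. In the check of lists, genes were drawn independently of each other and without a difference between the sets. All 5 raised lists were recovered in each comparison, with 0, 1 and 1 of 158 other lists called. False calls of lists with correlated genes or with a difference between the sets were not simulated. In the simulated interaction, 84.0% of 2-fold and 98.0% of 4-fold changes were recovered over 16087 genes with 3 false calls. Its spread was set by hand, and each section had the same effect in cortex and other spots, which the block removes. All 8 shifted lists were recovered in the simulated association test, with 1 false call among 25 others. There the lists were drawn independently of each other with a spread set by hand. These last 2 checks therefore show that the tests run as intended, not how often false calls arise in these sections.

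Alternatives were RLE instead of TMM scaling, no low-count filter, DESeq2 1.42.0, the version term, the 4 sections alone, the replicate number as a block, only the 2 ages compared, thinned totals and spots, spots under 1000 UMIs left out, mitochondrial and globin genes left out, other clustering resolutions, other association measures, and each section left out in turn. DESeq2 with the version term, the 4 sections alone for lists, cortex, interaction and association, the version by region as a term, the version term for association, and the version term with an estimated correlation were added after seeing the data. Clustering used Python 3.11.15, scikit-learn 1.9.0 and igraph 0.11.9, and the fits used R 4.3.3.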

Results

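Gene expression was mapped with Visium in 6 coronal sections of wild-type mouse brain, 2 each at P6, P12 and P60. The series title names brain neurovascular interactions and a role of TGF-beta signalling in the growth of brain vessels. P6 and P12 fall in the weeks after birth in which brain vessels still grow and myelin forms, and P60 is adult. The first and second sections held 2940 and 3105 spots at P6, 4366 and 3890 at P12, and 3901 and 3612 at P60. Their total counts were 79599758 and 15143813 UMIs at P6, 191100513 and 18032114 at P12, and 25152756 and 16493727 at P60. Median UMIs per spot were 26532 and 4624 at P6, 44685 and 4346.5 at P12, and 6386 and 4149.5 at P60. Mitochondrially encoded genes took 8.02% and 2.94% of the counts at P6, 9.41% and 5.37% at P12, and 8.68% and 8.01% at P60.

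The first sections of P6 and P12, labelled with another Space Ranger version than the other 4, differed from their partners of the same age. Sncb, the synuclein beta gene (chromosome 13, 54758860 to 54766622, GRCm38), had 368 CPM in the first P6 section and 4.79 CPM in the second. Its values at P12 were 613 and 5.04 CPM, and at P60 they were 9.04 and 23.2 CPM. Grin1, a subunit of the NMDA receptor (chromosome 2, 25291177 to 25319187), stood at 223 and 3.18 CPM at P6 and at 375 and 3.78 CPM at P12. In an edgeR fit with age and version, 3023 of 16331 genes differed with the version at an adjusted p under 0.05, with 2155 lower and 868 higher in the set of 4. Across genes, which are not independent replicates, the log2 ratios of first to second section correlated between P6 and P12 (Pearson r = 0.867). Of 9850 genes with a mean of at least 10 CPM, 720 were more than 4-fold apart between the sections of P6, 1257 at P12 and 103 at P60. For this reason values from the fit with the version term are given beside those of the age-only fit for the counts, the lists described and the leading genes.

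**Figure D1:**
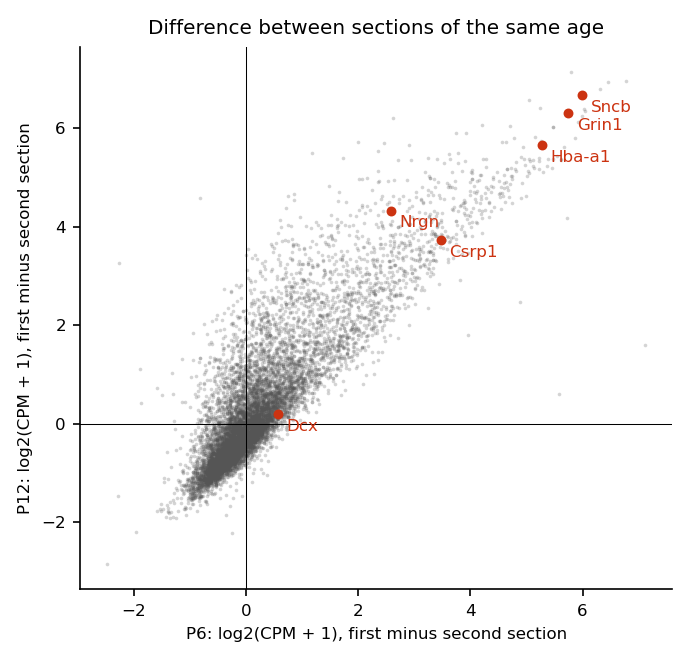
Each point is 1 of the 9850 genes with a mean of at least 10 CPM. The horizontal axis gives the log2 difference of CPM + 1 between the first and the second section at P6 and the vertical axis the same at P12, and the points rise together (Pearson r = 0.867 across genes), with Sncb, Grin1 and Hba-a1 far to the upper right.

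P60 was compared with P6 to describe the change from the growing to the adult brain. Genes of myelin, the insulating sheath that oligodendrocytes wrap around axons, led those that the naming rule took as rising. Mobp, a myelin protein gene (chromosome 9, 120149742 to 120181488), went from 2.83 ± 2.44 CPM at P6 to 1392 ± 218 CPM at P60 (SD, n = 2 sections each; log2 fold change 8.97, SE 0.97, edgeR adjusted p = 0.0434). Opalin, an oligodendrocyte membrane protein gene, went from 0.240 ± 0.150 to 181 ± 71.2 CPM (log2 fold change 9.73, SE 1.28, adjusted p = 0.0492). Mal, Ermn and Mag, all expressed by myelinating oligodendrocytes, rose by log2 fold changes of 7.87, 7.30 and 5.61. Pmch, the precursor of melanin-concentrating hormone made in the lateral hypothalamus, rose by 7.67 (SE 0.96). The coronal level of each section is not given in the sources used here. Whole-section changes of genes confined to 1 region, such as Pmch or those of the choroid plexus or meninges, are therefore not separated from the tissue that was sampled.

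The genes that the naming rule took as falling most between P6 and P60 included genes of young neurons and glial progenitors. Dcx, a microtubule protein gene of migrating neurons (chromosome X, 143855842 to 143933396), went from 253 ± 71.0 to 9.27 ± 0.680 CPM (log2 fold change -4.77, SE 0.32, edgeR adjusted p = 0.0434). Tubb2b, a beta tubulin of developing neurons with close paralogs, went from 2629 ± 1143 to 83.0 ± 15.4 CPM (-4.98, SE 0.57). Fabp7, a fatty acid binding protein gene of radial glia, went from 1467 ± 232 to 59.6 ± 9.87 CPM (-4.62, SE 0.39). Trim67, Cd24a and St8sia2, the last of which encodes an enzyme that adds polysialic acid to neural cell adhesion molecules, fell with log2 fold changes of -4.91, -4.72 and -4.60. In all, 263 of 16331 genes changed, 153 higher and 110 lower at P60. With the version term 2765 genes changed, 1587 higher and 1178 lower, and all 263 kept their direction and call. The version-term log2 fold changes were 8.62 for Mobp, 8.60 for Opalin, 7.31 for Mal, 7.48 for Pmch, -4.55 for Dcx, -4.46 for Tubb2b and -4.85 for Fabp7. Within the set of 4 sections, with 1 section of P6, 1621 genes changed. The count fell to 0 without either section of P6 or either section of P60, and it was 934 without the first and 657 without the second section of P12.

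**Figure D2:**
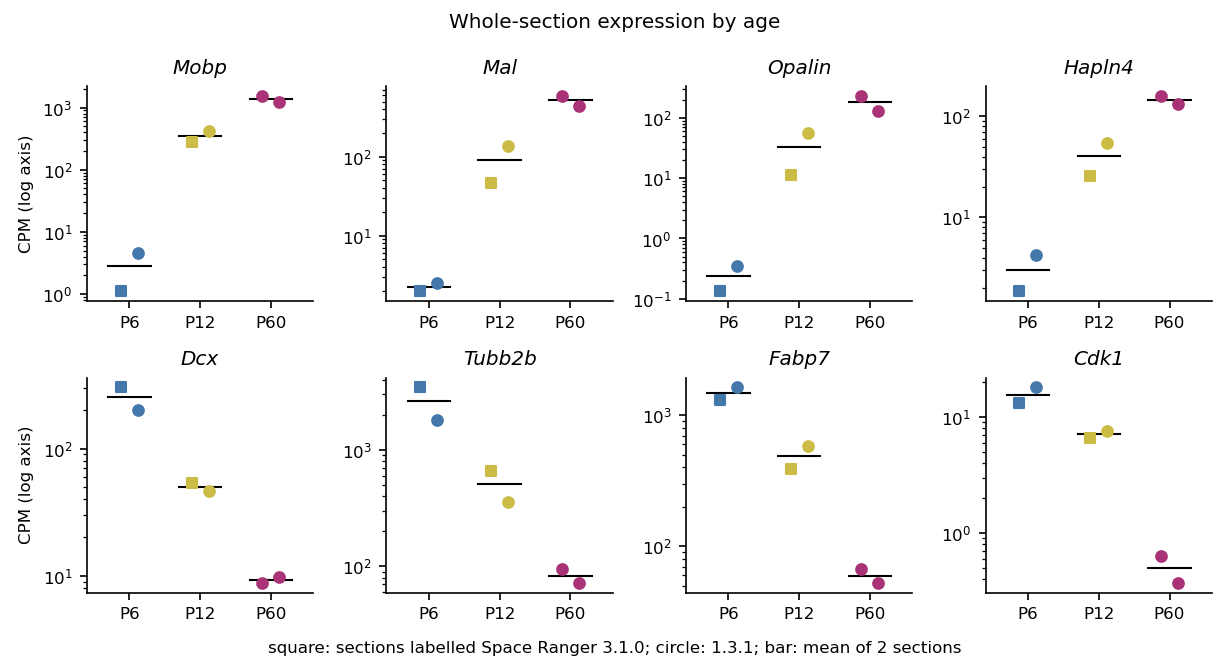
Whole-section expression in CPM, on log axes, of 8 genes at P6, P12 and P60; each point is 1 section, the bar is the mean of 2 sections, and squares mark the sections labelled Space Ranger 3.1.0. Mobp averaged 2.83, 345 and 1392 CPM at the 3 ages and Dcx 253, 50 and 9.27 CPM.

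Among the fixed lists, all 20 measured myelin genes were higher at P60 than at P6 and 16 passed the threshold over all genes (20 adjusted over the list alone). Their median log2 fold change was 4.88 (camera adjusted p = 1.0e-29; adjusted p = 0.135 with an estimated correlation). Klk6, an oligodendrocyte protease gene, went from 0.00668 ± 0.00945 to 21.8 ± 11.4 CPM. Of 29 cell division genes 5 fell (25 adjusted over the list alone), and the median was -2.87 (camera adjusted p = 6.3e-20; adjusted p = 0.0595 with an estimated correlation). Cdk1, the kinase that drives entry into mitosis, went from 15.5 ± 3.45 to 0.501 ± 0.182 CPM (log2 fold change -4.92, SE 0.44). Of 18 immature neuron genes 10 fell (16 adjusted over the list alone), and the median was -2.96 (camera adjusted p = 1.3e-19; adjusted p = 0.135 with an estimated correlation). Dpysl5, a regulator of neurite growth, went from 521 ± 165 to 23.2 ± 3.45 CPM. Of 12 radial glia genes 2 fell (6 adjusted over the list alone), and they were Fabp7 and Tnc, the latter with a log2 fold change of -3.08 (list adjusted p = 1.7e-05; adjusted p = 0.135 with an estimated correlation). Camera adjusted p-values of these 4 lists with the version term were 4.1e-57, 5.8e-24, 1.2e-33 and 8.0e-06, and 20 myelin genes rose and 21 cell division, 16 immature neuron and 6 radial glia genes fell in that fit.

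Glial and neuronal lists of mature tissue were higher at P60. Of 20 microglia genes 1 rose (9 adjusted over the list alone), with a median of 1.19 (camera adjusted p = 9.6e-07; adjusted p = 0.175 with an estimated correlation). That gene was Ctss, the protease cathepsin S, which went from 15.7 ± 0.476 to 84.7 ± 21.4 CPM. Of 19 astrocyte genes 3 rose (6 adjusted over the list alone), and the list passed at 2.7e-05 (adjusted p = 0.241 with an estimated correlation). Gjb6, the gap junction protein connexin 30, had a log2 fold change of 3.84 (SE 0.39) and Aldoc, a glycolytic enzyme of astrocytes, one of 2.56 (SE 0.34). Of 21 synapse genes 2 rose (8 adjusted over the list alone), Grin2a at 2.26 and Snap25 at 1.98 (list adjusted p = 0.000123; adjusted p = 0.135 with an estimated correlation). The immediate early list passed at 0.00956 (adjusted p = 0.385 with an estimated correlation) with 1 member past the threshold (5 adjusted over the list alone), Egr1, which had 25.6 ± 0.300 CPM at P6 and 211 ± 43.6 CPM at P60. The choroid plexus list passed at 0.0185 (adjusted p = 0.520 with an estimated correlation), with 1 of 11 genes past the threshold (4 adjusted over the list alone), Enpp2, which encodes autotaxin. The cholesterol synthesis and oligodendrocyte precursor lists were lower at P60, with medians of -0.96 and -0.85 (camera adjusted p = 0.000964 and 0.0262; adjusted p = 0.353 and 0.285 with an estimated correlation). In the first, 0 of 19 genes passed with edgeR (5 adjusted over the list alone), and in the second Vcan, the proteoglycan versican, was the 1 of 13 that did (2 adjusted over the list alone). Camera adjusted p-values in the fit with the version term were 8.0e-07 for microglia, 0.000259 for astrocytes, 0.000222 for synapses, 0.00177 for immediate early genes, 0.00571 for choroid plexus and 0.000340 for cholesterol synthesis. The oligodendrocyte precursor list did not pass with that term (adjusted p = 0.112). In the same fit 11 microglia, 8 astrocyte, 9 synapse, 4 immediate early and 5 choroid plexus genes rose, and 8 cholesterol synthesis and 2 precursor genes fell.

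Of the vascular lists, the basement membrane, fibroblast and smooth muscle lists passed with camera between P60 and P6, both with age only and with the version term. The basement membrane list, the sheet of matrix around vessels, had a median of -1.14 (camera adjusted p = 0.000158; adjusted p = 0.135 with an estimated correlation), and 0 of its 17 genes passed with edgeR over all genes (9 adjusted over the list alone). Nid2, which links laminin and collagen in that sheet, stood at 10.9 ± 3.64 and 1.24 ± 0.0897 CPM (edgeR adjusted p = 0.0611 with age only and 0.0128 with the version term). In the fibroblast and meninges list, with a median of -0.83 (camera adjusted p = 0.00166; adjusted p = 0.489 with an estimated correlation), Col3a1, a fibrillar collagen gene, went from 30.8 ± 14.3 to 1.89 ± 0.230 CPM (log2 fold change -4.03, SE 0.54, adjusted p = 0.0491). It was the 1 of 15 genes past the threshold (2 adjusted over the list alone). Clusters named meninges held 210 and 109 spots at P6 and 192 in the second P60 section, and the first P60 section had none. In cortex spots 0 of 5 tested genes of this list passed with age only, with a median of -0.24 (0.02 with the version term). The whole-section fall is therefore not separated from how much meninges each section held. All 11 smooth muscle genes had higher fitted values at P60, with a median of 1.31 (camera adjusted p = 0.00169; adjusted p = 0.385 with an estimated correlation). None passed with edgeR over all genes (2 adjusted over the list alone), and Myh11, the smooth muscle myosin heavy chain, stood at 1.68 ± 0.830 and 8.76 ± 1.94 CPM. In the fit with the version term the camera adjusted p-values were 0.000781 for basement membrane, 0.00159 for fibroblasts and meninges and 0.000222 for smooth muscle. There 7 basement membrane and 4 fibroblast genes fell and 5 smooth muscle genes rose, with a smooth muscle median of 2.21.

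The endothelial lists did not move as sets, but single members did. Kdr, the main VEGF receptor of endothelium (chromosome 5, 75932827 to 75979072), went from 24.1 ± 1.16 CPM at P6 to 5.58 ± 0.960 CPM at P60 (log2 fold change -2.11, SE 0.27, edgeR adjusted p = 0.0476; version-term log2 fold change -2.12, adjusted p = 0.0136). Slco1a4, an organic anion transporter of the blood-brain barrier (chromosome 6, 141805438 to 141856284), went from 6.71 ± 0.506 to 38.0 ± 8.73 CPM (log2 fold change 2.5, SE 0.30, adjusted p = 0.0436; 0.0132 with the version term). With the version term Cd93, an endothelial receptor gene, also fell, with a log2 fold change of -2.10 (adjusted p = 0.0154), and Ly6a and Ly6c1, surface antigen genes of endothelium with close paralogs, rose by 3.44 and 2.80 (adjusted p = 0.00927 and 0.0112). These 3 had adjusted p of 0.0541, 0.0545 and 0.0521 with age only. The pan-endothelial list had a median of -0.11 over 21 genes (camera adjusted p = 0.606), and the barrier list one of -0.22 over 17 genes (0.837). Called members were 1 lower and 1 higher in these lists with age only, and 2 higher and 3 lower and 2 higher and 1 lower with the version term. The VEGF, Notch and angiopoietin list passed with age only, with a median of -0.76 (camera adjusted p = 0.0185; adjusted p = 0.385 with an estimated correlation), but not with the version term (adjusted p = 0.112) or in the 4 sections (0.0566). Kdr was the 1 of its 21 genes past the threshold (2 adjusted over the list alone), and 2 passed with the version term.

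**Figure D3:**
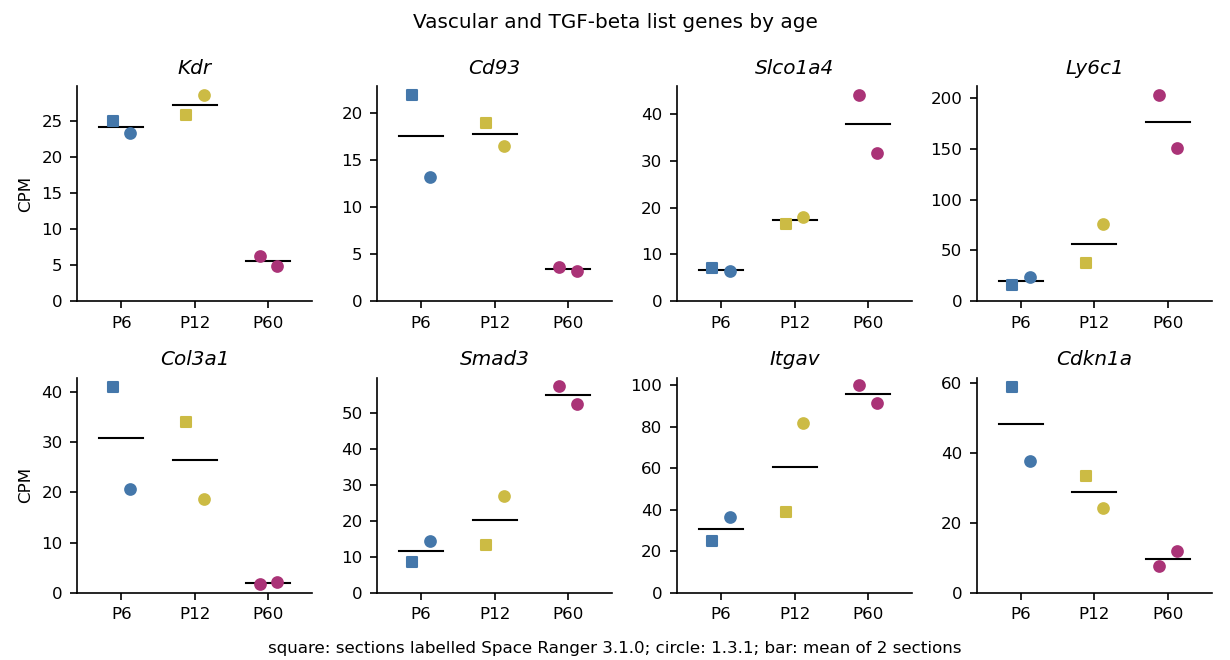
Whole-section expression in CPM of 8 vascular and TGF-beta list genes at P6, P12 and P60; points are sections, bars are means of 2 sections, and squares mark the sections labelled Space Ranger 3.1.0. Kdr averaged 24.1, 27.2 and 5.58 CPM at the 3 ages and Slco1a4 averaged 6.71, 17.3 and 38.0 CPM.

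TGF-beta genes were of particular interest because of the series title. Of 52 tested members of the 3 TGF-beta lists, 0 changed between P6 and P60 in the age-only edgeR fit, and 8 changed with the version term. Over all genes 2765 of 16331 changed with that term, so the TGF-beta list genes did not change more often than genes at large. Smad3, which carries the TGF-beta signal to the nucleus (chromosome 9, 63646766 to 63757994), stood at 11.4 ± 4.14 CPM at P6 and 54.9 ± 3.49 CPM at P60. Its log2 fold change was 2.26 (SE 0.47, adjusted p = 0.0758) with age only and 1.87 (adjusted p = 0.0132) with the version term. With that term Itgav, the integrin alpha V subunit that can release latent TGF-beta, rose by 1.26 (adjusted p = 0.0282), and so did the signal inhibitor Smad7 (1.47, 0.0440) and the target gene Tagln (2.75, 0.0351). The 4 that fell with the term were the fibrillin genes Fbn2 (-2.47, adjusted p = 0.0157) and Fbn1 (-1.29, 0.0359), the cell cycle inhibitor Cdkn1a (-2.01, 0.0181) and fibronectin, Fn1 (-1.28, 0.0299). The ligands Tgfb2 and Tgfb3 stood at 35.4 ± 3.21 and 5.29 ± 1.01 CPM at P6 and at 18.1 ± 5.55 and 11.2 ± 1.32 CPM at P60 (adjusted p = 0.207 and 0.166). The receptors Tgfbr1 and Tgfbr2 stood at 29.3 ± 0.570 and 13.6 ± 2.76 CPM at P6 and at 22.2 ± 4.12 and 14.7 ± 2.27 CPM at P60 (adjusted p = 0.561 and 0.873). Tgfb1 had 155 and 223 UMIs in the first sections of P6 and P12 and 0 in each of the other 4. A count of 0 there allows up to 0.198, 0.166, 0.119 and 0.182 CPM in the second P6, second P12 and the P60 sections, for counting error only. A comparison of Tgfb1 with P60 was therefore not possible apart from the set of sections. Between P12 and P6 its version-term log2 fold change was -0.75 (SE 0.48, adjusted p = 0.475), a value that rests on the 2 first sections, with 2.07 CPM at P6 and 1.23 CPM at P12. As lists, the TGF-beta ligands and the receptors did not pass (camera adjusted p = 0.376 and 0.966). The target genes passed with age only, with a median of -1.11 (0.0386; adjusted p = 0.520 with an estimated correlation), but not with the version term, where the median was -0.37 (adjusted p = 0.370), or in the 4 sections (0.219). Of their 20 genes 0 passed over all genes, 1 adjusted over the list alone and 4 with the version term.

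The remaining lists did not pass for P60 against P6 with age only. Their camera adjusted p-values were 0.514 for tip cells, 0.900 for arterial and 0.201 for venous endothelium, 0.514 for pericytes, 0.101 for Wnt beta-catenin, 0.0622 for hypoxia response, 0.201 for inhibitory neurons, 0.101 for activated microglia, 0.234 for perivascular macrophages, 0.660 for red blood cells, 0.471 for ependyma, 0.522 for brain extracellular matrix, 0.104 for mitochondrially encoded and 0.480 for ribosomal protein genes. The arterial and macrophage lists had medians of 0.02 and 0.01 although their test pointed down. With the version term the mitochondrially encoded list was higher at P60 (median 1.58, adjusted p = 2.3e-05; adjusted p = 0.518 with an estimated correlation) and the activated microglia list lower (median -0.81, adjusted p = 0.0137; adjusted p = 0.518 with an estimated correlation). The term treats the P60 sections as alike, although they differed along the gene pattern that separates the sets. How far this made these list shifts was not tested. The version term turned the median of the red blood cell list from -0.21 to 1.5 and that of the ribosomal list from -0.34 to 0.70, and the medians of the tip cell, TGF-beta ligand and macrophage lists also changed sign, from -0.29 to 0.18, from -0.56 to 0.03 and from 0.01 to -0.08. Of the 9 brain extracellular matrix genes, with a median of -0.35, 2 rose, the link protein genes Hapln4 (3.04 ± 1.67 to 147 ± 18.5 CPM) and Hapln2, and 2 fell, Vcan and Tnc (2 and 3 with the version term). Of the 12 inhibitory neuron genes 2 rose: Kcnc2 and Kcnc1, potassium channels of fast-spiking interneurons, had log2 fold changes of 2.47 and 1.68 (4 rose and 2 fell with the version term). Lpl, a lipase gene of the activated microglia list, was the 1 of its 8 genes that fell (-2.70, SE 0.28, edgeR adjusted p = 0.0434), and 2 fell with the version term. It was also among the 10 leading genes of P6 clusters that scored highest for hippocampal formation, so its fall cannot be assigned to microglia. Where it fell was not tested. In all, 16 of 34 lists passed, 7 higher and 9 lower at P60, and 15 passed with the version term.

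**Figure D4:**
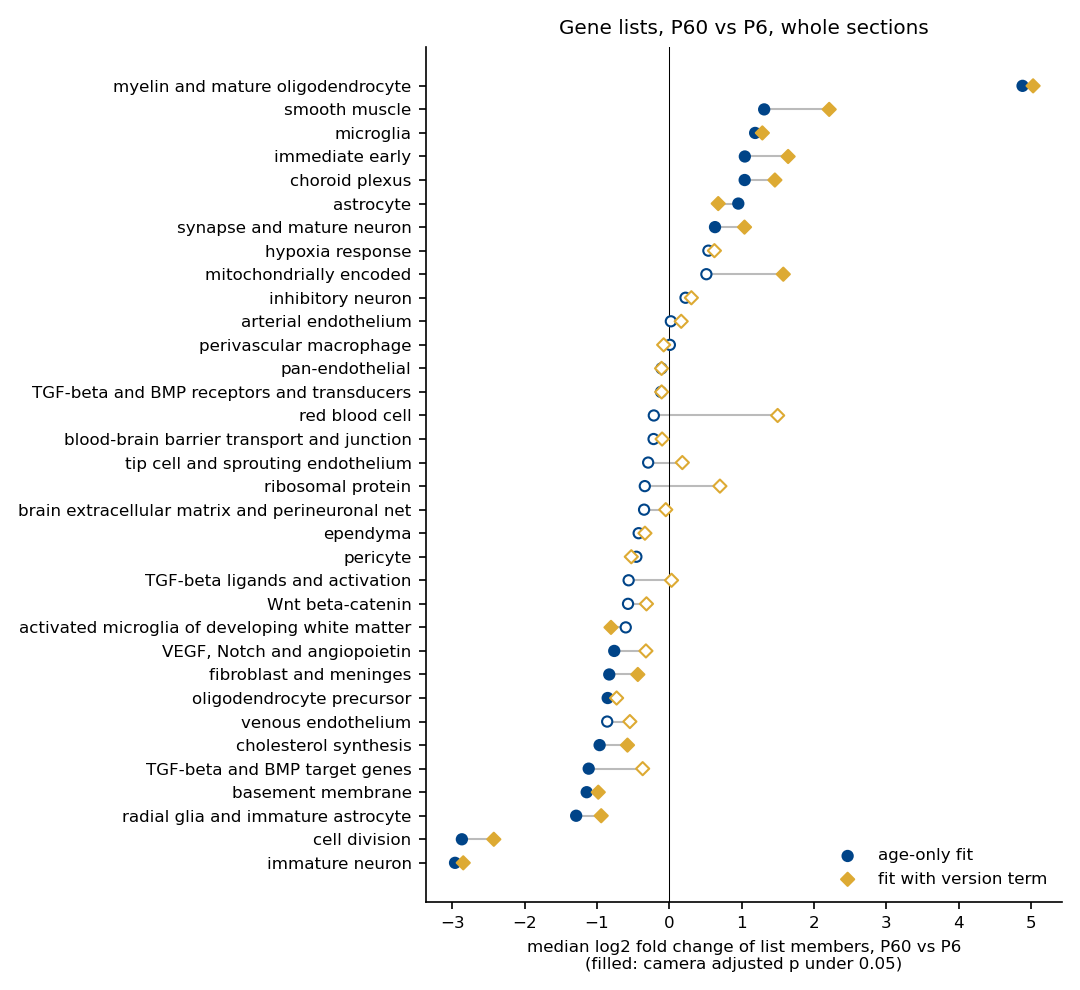
Median log2 fold change of the members of each of the 34 lists for P60 against P6, from the age-only fit (circles) and from the fit with the version term (diamonds), with filled symbols for a camera adjusted p under 0.05. Myelin has medians of 4.88 and 5.03 and immature neurons of -2.96 and -2.85 in the 2 fits.

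P12 was compared with P6 for the change over the second postnatal week. The myelin list was higher at P12 in all 20 members, with a median of 4.37 (camera adjusted p = 9.7e-45; adjusted p = 0.119 with an estimated correlation). With age only 0 of them passed over all genes with edgeR (20 adjusted over the list alone), and with the version term 12 did. Mobp went from 2.83 ± 2.44 to 345 ± 96.8 CPM (version-term log2 fold change 7.24, SE 0.51, adjusted p = 0.0350). Mog, Opalin, Mal and Ermn, which are all expressed by oligodendrocytes, rose in the same fit by 7.31, 6.78, 5.13 and 4.95. Trim67, St8sia2 and Dcx fell, with log2 fold changes of -3.25, -3.16 and -2.32 (adjusted p = 0.0350 each). Dcx had 50 ± 5.01 CPM at P12.

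Over all genes, the age-only edgeR fit called 0 genes between P12 and P6, with 1291 at an unadjusted p under 0.05 and a smallest adjusted p of 0.372. The fit with the version term called 41 genes, 33 higher and 8 lower at P12, and DESeq2 gave 432 without and 1321 with the version term. The 4 sections alone gave 264, but they hold 1 section each of P6 and P12, so the spread comes from the 2 sections of P60 and the count says nothing of spread at P6 or P12. Lists also lower at P12 were immature neurons (median -1.26, camera adjusted p = 3.8e-16; adjusted p = 0.119 with an estimated correlation), cell division (-0.64, 3.8e-07; adjusted p = 0.119 with an estimated correlation), radial glia (-0.68, 0.000577; adjusted p = 0.234 with an estimated correlation) and ribosomal proteins (-0.50, 0.00427; adjusted p = 0.671 with an estimated correlation). Higher at P12 were synapse genes (median 0.77, adjusted p = 1.1e-07; adjusted p = 0.119 with an estimated correlation), microglia (1.06, 2.1e-09; adjusted p = 0.136 with an estimated correlation) and astrocytes (0.63, 6.2e-06; adjusted p = 0.234 with an estimated correlation). Immediate early genes (1.18, 2.0e-05; adjusted p = 0.234 with an estimated correlation) and choroid plexus genes (0.45, 0.0211; adjusted p = 0.672 with an estimated correlation) were higher too, the last not with the version term (adjusted p = 0.0772). P2ry12, a purinergic receptor of microglia, stood at 10.7 ± 1.36 and 38.3 ± 2.31 CPM, and Egr1 at 25.6 ± 0.300 and 105 ± 31.1 CPM (edgeR adjusted p = 0.372 each with age only). Adding the version term gave camera adjusted p-values of 1.1e-89 for myelin, 1.1e-20 for immature neurons, 3.4e-06 for cell division, 0.000697 for radial glia, 0.000377 for ribosomal proteins, 8.1e-07 for synapses, 6.9e-09 for microglia, 1.5e-06 for astrocytes and 2.0e-05 for immediate early genes. That fit also placed the mitochondrially encoded list higher at P12 (adjusted p = 0.00904; adjusted p = 0.725 with an estimated correlation), and its median difference was 0.07 between the first and 1.02 between the second sections. The median difference of the ribosomal list was -0.54 between the first and -0.48 between the second sections of the 2 ages. Between the second sections of the 2 ages, which belong to the set of 4, the median difference was -0.67 for ependyma and 0.36 for choroid plexus genes. The choroid plexus list did not pass in that set. The other 24 lists did not pass with age only, including ependyma (camera adjusted p = 0.0911, and 0.671 with an estimated correlation). Among them the pan-endothelial list had a median of 0.15 (camera adjusted p = 0.164, and 0.0392, pointing up, in the 4 sections with 1 section of each of the 2 ages) and the TGF-beta ligands, receptors and targets had adjusted p of 0.993, 0.820 and 0.947. Slco1a4 stood at 17.3 ± 1.08 CPM at P12 (log2 fold change 1.36, SE 0.28, edgeR adjusted p = 0.421 with age only and 0.0869 with the version term).

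P60 was compared with P12 for the change after the second week. Cell division genes were lower at P60, with a median of -2.38 over 29 genes (camera adjusted p = 2.1e-18; adjusted p = 0.0654 with an estimated correlation), and immature neuron genes had a median of -1.70 (3.9e-15; adjusted p = 0.164 with an estimated correlation). Cdk1 stood at 7.07 ± 0.695 CPM at P12 and 0.501 ± 0.182 CPM at P60 (log2 fold change -3.79, SE 0.42, edgeR adjusted p = 0.228 with age only and 0.0551 with the version term). Myelin genes were higher still at P60, with a median of 1.97 (camera adjusted p = 3.6e-12; adjusted p = 0.319 with an estimated correlation), and Trf, the transferrin gene, stood at 65.2 ± 3.30 and 299 ± 80.8 CPM. Kdr stood at 27.2 ± 2.05 CPM at P12 and 5.58 ± 0.960 CPM at P60 (log2 fold change -2.28, SE 0.28), and Col3a1 at 26.4 ± 10.9 and 1.89 ± 0.230 CPM, with edgeR adjusted p of 0.228 for both with age only and 0.0551 with the version term.

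The age-only edgeR fit called 0 of 16331 genes between P60 and P12, with 1992 at an unadjusted p under 0.05 and a smallest adjusted p of 0.228. The fit with the version term also called 0, with 4585 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0551. The 4 sections alone, with 1 section of P12, gave 1374 genes, and DESeq2 gave 826 without and 3034 with the version term. Lists lower at P60 with age only and with the version term were basement membrane (median -0.87, camera adjusted p = 8.3e-05; adjusted p = 0.199 with an estimated correlation), fibroblast and meninges (-0.51, 0.00507; adjusted p = 0.518 with an estimated correlation), radial glia (-0.78, 0.00112; adjusted p = 0.298 with an estimated correlation), oligodendrocyte precursors (-0.73, 0.00501; adjusted p = 0.298 with an estimated correlation) and cholesterol synthesis (-0.62, 0.00112; adjusted p = 0.467 with an estimated correlation). Smooth muscle genes were higher (median 1.38, adjusted p = 0.00112; adjusted p = 0.467 with an estimated correlation). Adding the version as a term gave camera adjusted p-values of 4.6e-19 for cell division, 4.9e-17 for immature neurons, 9.4e-08 for myelin, 0.00142 for basement membrane, 0.00867 for fibroblasts and meninges, 0.00315 for radial glia, 0.0328 for oligodendrocyte precursors, 0.000990 for cholesterol synthesis and 0.000169 for smooth muscle. Within the set of 4 sections the radial glia, precursor and fibroblast lists did not pass (adjusted p = 0.0516, 0.0696 and 0.0957). The TGF-beta target, Wnt beta-catenin, and VEGF, Notch and angiopoietin lists were lower and the astrocyte list higher with age only (adjusted p = 0.0107, 0.0115, 0.0220 and 0.0348; adjusted p = 0.467 with an estimated correlation in each). None of these 4 passed with the version term, where the adjusted p-values were 0.318, 0.0850, 0.207 and 0.336. Higher at P60 with the version term alone were ribosomal protein genes, whose median went from 0.12 to 1.55 (adjusted p = 0.000135; adjusted p = 0.573 with an estimated correlation), and mitochondrially encoded genes, from 0.22 to 0.96 (adjusted p = 0.000807; adjusted p = 0.680 with an estimated correlation). Genes with a ribosomal protein symbol took 6.19% and 5.31% of the counts in the first and second P12 sections and 6.18% and 6.51% at P60. The version term treats the P60 sections as alike, although they differed along the gene pattern that separates the sets. These 2 shifts are therefore not read as changes with age. The other 21 lists did not pass with age only, among them the pan-endothelial list (median -0.25, camera adjusted p = 0.158) and the TGF-beta ligands and receptors (0.221 and 0.831). The count of lists was 13 with all sections and 7 without the first section of P12.

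Within cerebral cortex, spots were compared between ages so that regions outside the cortex did not enter. Hapln4 went from 0.531 ± 0.0536 CPM at P6 to 200 ± 3.50 CPM at P60 (log2 fold change 8.49, SE 0.63, edgeR adjusted p = 0.0343). Ankrd33b, Fam107a, a gene of astrocytes and some neurons, and Il33, which encodes the alarmin interleukin 33, rose by 6.35, 5.63 and 5.38. Dpysl3, a cytoskeletal regulator of growing neurites, went from 887 ± 528 to 4.20 ± 1.08 CPM (log2 fold change -7.71, SE 1.26, adjusted p = 0.0495), and St8sia2, Trim67, Dpysl5 and Tubb2b fell with log2 fold changes of -7.19, -6.30, -6.01 and -6.00. Pvalb, the calcium buffer of a class of interneurons, had 525 ± 20.8 CPM at P60, but it led clusters of the P60 cortex and its difference is not read as a change. The version-term log2 fold changes of Hapln4 and Dpysl3 were 7.80 and -6.61, with adjusted p of 0.00765 and 0.00773.

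In cortex 516 of 13578 genes changed between P60 and P6 with edgeR, 316 higher and 200 lower. With the version term the number was 2499, of which 1451 were higher, and within the set of 4 sections it was 2665. The count was 0 without any 1 of the sections of P6 or P60, 1180 without the first and 1083 without the second P12 section. For P12 against P6 the age-only fit called 0 genes (1351 at an unadjusted p under 0.05), the version term 275 and the 4 sections, with 1 section each of P6 and P12, 1072. For P60 against P12 both fits called 0 (1709 and 3815 at an unadjusted p under 0.05), and the 4 sections called 2143. The pan-endothelial list had 2 genes higher and 1 lower in cortex at P60 than at P6, out of 21 (2 and 2 adjusted over the list alone, 3 and 3 with the version term), and the basement membrane list 1 lower of 17 (7 adjusted over the list alone, 7 with the version term). Of the TGF-beta lists 1 of 19 receptor and transducer genes was higher, and 0 of 14 ligand and 0 of 16 target genes passed with edgeR over all genes. Adjusted over the list alone, 1 receptor gene was higher, 2 ligand genes were higher and 2 lower, and 1 target gene was higher and 3 lower. The version-term fit called 1 receptor gene higher and 2 lower, 2 ligand genes higher and 3 lower, and 1 target gene higher and 2 lower.

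The interaction test asked which vascular and signalling genes changed differently in cortex than in the rest of the section between P6 and P60. Sparc, a matrix glycoprotein gene of vessels and glia (chromosome 11, 55394159 to 55420080), was 1.02 ± 0.02 log2 units lower in cortex than elsewhere at P6, as a cortex-minus-other value of -1.02, and its value at P60 was -2.72 ± 0.04. The change was -1.71 (SE 0.10, edgeR adjusted p = 2.6e-12). Lamb1, a laminin chain of basement membranes, went from 0.06 ± 0.01 to -1.81 ± 0.09 (change -2.08, SE 0.20, adjusted p = 2.3e-08), and the type I TGF-beta receptor Tgfbr1 (chromosome 4, 47353222 to 47414926) from 0.90 ± 0.06 to -0.30 ± 0.18 (change -1.20, SE 0.16, adjusted p = 5.2e-06). In the other direction, Itgav (chromosome 2, 83722303 to 83806917) went from -0.49 ± 0.04 to 0.79 ± 0.04 (change 1.31, SE 0.12, adjusted p = 7.7e-09). Cdkn1a went from -1.40 ± 0.20 to 0.68 ± 0.00 (2.12, SE 0.20) and Pdgfb, a growth factor gene that recruits pericytes, from -0.39 ± 0.01 to 0.56 ± 0.04 (0.98, SE 0.13). Values are mean ± SD of 2 sections on the log2 scale of CPM + 1, and the SE belongs to the fitted change.

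Among TGF-beta list genes that rose in cortex relative to other spots were also Klf10, an early target gene (1.14, SE 0.17), Smad3 (0.85, SE 0.17) and the repressor Skil (0.74, SE 0.12). Tgfb3 (1.17, SE 0.28) and Lrrc32 (1.42, SE 0.40) did so too. Besides Tgfbr1, the called TGF-beta list genes against cortex were Fbn2 (-1.77, SE 0.42), Acvr1 (-0.63, SE 0.14), Furin (-0.58, SE 0.17), Smad4 (-0.58, SE 0.19) and Timp3 (-0.33, SE 0.11). The TGF-beta list genes thus moved in both directions. In all, 29 of 204 tested list genes differed at an adjusted p under 0.05 over all genes, 17 in favour of cortex and 12 against it (28 adjusted over the list alone). Over the whole transcriptome 2699 of 16087 genes did, 1312 in favour of cortex, so the list genes did not differ more often than genes at large. Within the set of 4 sections the changes were -1.66 for Sparc, -2.02 for Lamb1, -1.21 for Tgfbr1, 1.31 for Itgav, 2.38 for Cdkn1a and 1.01 for Pdgfb. With the version by region as a term, 30 list genes differed. The count was 18 without the first P60 section.

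**Figure D5:**
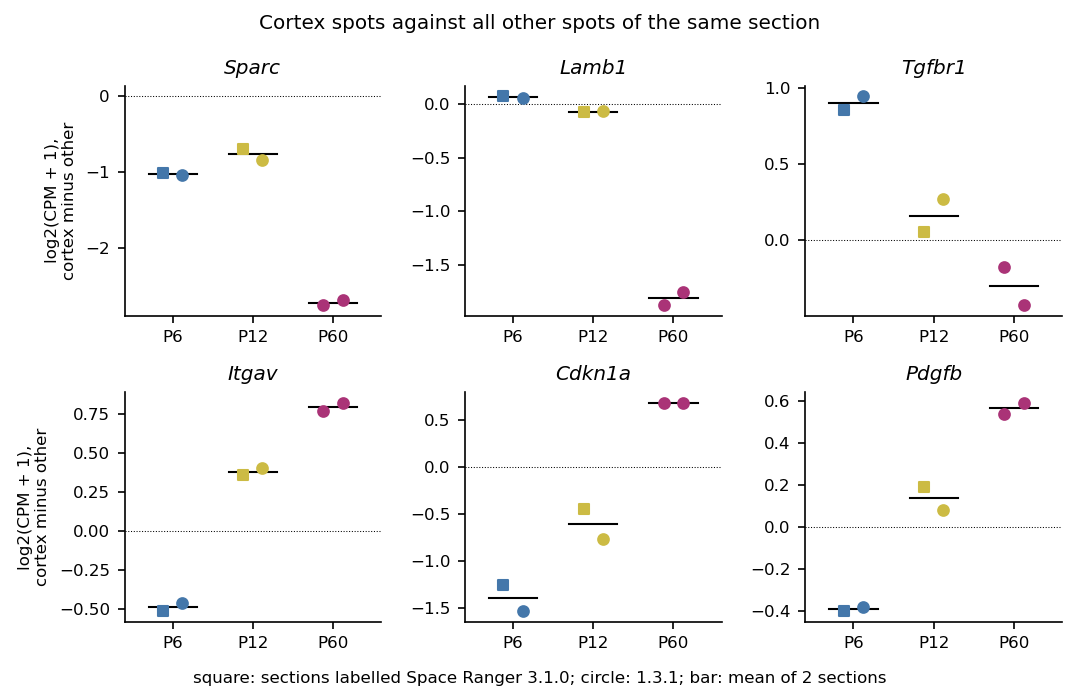
Log2 CPM + 1 in cortex spots minus that in all other spots of the same section, for 6 genes at P6, P12 and P60; points are sections, bars are means of 2 sections, and squares mark the sections labelled Space Ranger 3.1.0. Sparc lies at -1.02, -0.76 and -2.72 and Itgav at -0.49, 0.38 and 0.79 on average at the 3 ages.

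The association test asked which lists were found in the same spots as endothelial transcripts, which bears on the neurovascular aim in the series title. Basement membrane genes were positively associated with the pan-endothelial list across spots at P6, with a mean rho of 0.170 ± 0.00474 (SD, n = 2 sections), and less so at P60, at 0.0927 ± 0.0215 (limma adjusted p = 0.0318). Ribosomal protein genes went from 0.164 ± 0.0366 to 0.0529 ± 0.0218 and cell division genes from 0.101 ± 0.0325 to -0.00913 ± 0.0225 (adjusted p = 0.0253 each). Immature neuron genes were negatively associated, at -0.151 ± 0.00112 at P6 and -0.0627 ± 0.00133 at P60 (adjusted p = 0.0253). Astrocyte and myelin genes had values of 0.119 ± 0.0180 and 0.0821 ± 0.0196 at P6 and of 0.169 ± 0.00370 and 0.132 ± 0.0416 at P60, cholesterol synthesis genes of -0.0696 ± 0.00500 and -0.0229 ± 3.1e-05, and fibroblast genes of 0.174 ± 0.0214 and 0.0786 ± 0.00770, none of which passed (adjusted p = 0.165, 0.165, 0.137 and 0.0795).

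In all, 4 of 33 lists differed between P60 and P6, 1 with a higher and 3 with a lower rho. With the version term 8 lists differed, and the adjusted p of the 4 lists were 0.0247 for basement membrane, 0.00487 for ribosomal protein, 0.00487 for cell division and 0.0117 for immature neuron genes. Within the set of 4 sections 0 lists passed with limma, with 15 at an unadjusted p under 0.05. The count was 0 without either P6 section, 1 without either P60 section, and 10 without either P12 section. After the sums were centred within each cluster 0 lists passed, with 4 at an unadjusted p under 0.05 and adjusted p of 0.239, 0.610, 0.0850 and 0.153 for the same 4 lists. The TGF-beta target list had a rho of 0.114 ± 0.00525 at P6 and 0.0431 ± 0.0206 at P60 (adjusted p = 0.0582, and 0.0253 with the version term). For P12 against P6 and for P60 against P12, 0 lists passed with limma, with 4 and 5 at an unadjusted p under 0.05. Thinned spots held on average 0.747 to 1.14 UMIs of the pan-endothelial list, so that each rho rests on sparse counts.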

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

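The tests against gene density, header version and the version by region as a term in this part were chosen only after the results they bear on were seen.

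In the interaction of region with age, 29 of the 204 vascular and signalling list genes changed differently in cortex spots than in the other spots of the same sections between P6 and P60, by a test of the difference itself. Over all genes 2699 of 16087 did, so such a difference was no more frequent among the list genes than among genes at large. Of these, 9 genes were followed through the alternatives, with log2 changes of the cortex-minus-other value. They were Sparc (-1.71), Lamb1 (-2.08) and Tgfbr1 (-1.20) against cortex and Itgav (1.31), Cdkn1a (2.12), Pdgfb (0.98), Klf10 (1.14), Skil (0.74) and Smad3 (0.85) in favour of cortex. Each of these 9 genes kept its direction and call in all 12 alternatives, including each section left out in turn.

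A difference between the 2 sets of sections as the whole cause is argued against by the fit with the version by region as a term, in which 23 of the 29 genes kept their direction and call. A change with age in the mix of regions among the other spots could account for part of the pattern. With thalamus spots in place of all other spots, 18 of the 29 genes kept their direction and call, which lies between the bounds set beforehand, so this explanation stays open for the set. Sparc went against it, with a change of -2.90 (SE 0.15) against thalamus, and so did Lamb1, Tgfbr1, Itgav, Cdkn1a, Pdgfb, Klf10, Skil and Smad3, while of the 11 genes not kept Vtn (-0.42), Rgs5 (-0.17), Esam (-0.04), Ly6c1 (-0.04) and Ackr1 (0.10) changed sign, Tgfb3, Fbn2, Ly6a, Lrrc32 and Timp3 had the same sign but did not pass, and Gja5 was not tested there. A biological change with age in vessels or glia, in cortex or elsewhere, was not tested. For Sparc and Cdkn1a the larger move lay in the other spots, which include clusters that scored highest for cortex but were kept out of the class. Sparc had 151 and 239 CPM in cortex spots at P6 and 156 and 133 CPM at P60. In other spots Sparc had 306 and 492 CPM at P6 and 1058 and 866 CPM at P60. Cdkn1a went from 65.1 and 45.3 to 6.17 and 10.1 CPM in other spots.

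The difference between the 2 sets of sections is the second pattern, since 2155 genes were lower in the set of 4 at the same age. Unequal counting precision as the whole cause is argued against, because 73.1% of these genes were still lower after every section was thinned to 15143813 UMIs. Random thinning leaves the expected share of each gene unchanged, so it cannot decide on other effects of lower sequencing depth. Base composition could contribute: the genome sequence was not used here, and gene density served in its place, because gene-dense stretches tend to be rich in G and C. The genes lower in the set of 4 had a median of 39 annotated neighbours within 500 kb, against 26 to 27 in 1000 draws of genes matched on mean CPM, and 26 for the genes that were higher. Whether the Space Ranger version is the cause cannot be told apart from library preparation or sequencing, since the headers of 2 first-set matrices name the version that the notes give to the other set.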

How the results depend on the processing

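Tests with DESeq2 and the version term, with the 4 sections alone for lists, cortex, interaction and association, and with the version term in the association and with an estimated correlation were chosen only after the results had been seen. No value of a named gene that passed its test changed sign under any alternative. Over 2642 values of named genes under alternatives, 2102 stayed on their side of the threshold, 282 fell below it, 251 moved past it, and 7, all uncalled, changed sign or went to 0. For the interaction, these values cover only the genes followed through the alternatives above. The cause of the moves below was not tested, except that sections left out and thinned counts leave less data.

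For P60 against P6 the 263 genes became 2765 with the version term, 1621 with the 4 sections alone, 473 without a low-count filter, 1099 with only these 2 ages, 142 with thinned totals, 98 with thinned spots, 2606 with DESeq2 and 4336 with DESeq2 and the version term. For P12 against P6 the 0 genes became 41, 264, 432 and 1321 with the version term, the 4 sections alone, DESeq2 and DESeq2 with the version term. For P60 against P12 the 0 became 1374, 826 and 3034 in the last 3. Lists passing were 0 in all 3 comparisons with an estimated correlation, with or without the version term, and 8 for P60 against P12 in the 4 sections. In cortex the 516 genes became 2499 with the version term, 778 without a filter and 2665 in the 4 sections, P12 against P6 became 275, 1 and 1072, and P60 against P12 became 2143 in the 4 sections. Associated lists became 9 when thinned to 1000 UMIs, 9 with Pearson's r, 8 with the version term, and 0 when centred or in the 4 sections.

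With 1 section left out at a time, genes ranged from 0 to 0 for P12 against P6 and for P60 against P12 and from 0 to 934 for P60 against P6. Lists ranged from 9 to 12, 7 to 15 and 14 to 16, cortex genes from 0 to 0, 0 to 0 and 0 to 1180, interaction genes from 18 to 34 and associated lists from 0 to 10. A section left alone at its age was assumed to vary like the others.

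With the replicate number as a block, the P60 against P6 counts were 0 in whole sections and 0 in cortex. Deviations of same-numbered sections correlated at 0.867 for P6 with P12, -0.683 for P6 with P60 and -0.673 for P12 with P60, so the number does not pair the sections of all 3 ages. For P6 and P12 it coincides with the set of sections. The 2 P60 sections, though of the same set, thus differed along the gene pattern that separates the sets. The first principal component held 56.8% of the variance. On it the first and second sections lay at -68.7 and 29.9 at P6, -61.8 and 75.5 at P12, and 30.1 and -5.00 at P60. The version term treats the P60 sections as alike in this pattern, and how far that alters comparisons with P60 was not tested.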

Other observations

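The comparison of thalamus spots, and the tests that read the size of the association after centring as a sign of its cause, were chosen only after the results had been seen. Centring itself, and the test with matched counts, had been chosen beforehand.

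Thalamus spots also changed between P6 and P60. Ermn, an oligodendrocyte cytoskeletal gene, went from 0.162 ± 0.229 to 93.2 ± 15.2 CPM (SD, n = 2 sections; log2 fold change 9.97, SE 1.17, edgeR adjusted p = 0.0312). Gabrd, the delta subunit of the GABA-A receptor that carries tonic inhibition in thalamic relay neurons, went from 1.33 ± 0.511 to 275 ± 13.4 CPM (log2 fold change 7.59, SE 0.44, adjusted p = 0.0304). Hapln4 rose there too, with a log2 fold change of 7.31, as did Ptgds, a prostaglandin D synthase (7.01), and Abhd12b (8.27). Stk32b, a kinase gene, went from 54.6 ± 1.5 to 1.15 ± 0.693 CPM (-5.65, SE 0.55), and Slc10a4, a vesicular transporter gene, from 65.8 ± 2.96 to 2.66 ± 0.284 CPM (-4.61, SE 0.33). Tubb2b, St8sia2 and Fabp7 fell as well, with log2 fold changes of -5.37, -5.29 and -4.81. Log2 fold changes with the version term were 9.17 for Ermn, 7.36 for Abhd12b, 7.39 for Gabrd, 6.67 for Hapln4, 7.60 for Ptgds, -5.84 for Stk32b, -4.89 for Tubb2b, -4.45 for St8sia2, -5.11 for Fabp7 and -4.58 for Slc10a4.

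In all, 486 of 13218 genes changed in thalamus spots between P60 and P6 with edgeR, 278 higher and 208 lower. With the version term the number was 2869 and within the set of 4 sections, with 1 section of P6, it was 2511. For P12 against P6 the age-only fit called 0 genes (1474 at an unadjusted p under 0.05) and the version term 894, and for P60 against P12 they called 0 (1505 at an unadjusted p under 0.05) and 977. Whether any of these changes differed from those in cortex was not tested gene by gene here, beyond the vascular list genes.

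The association of 4 lists with endothelial transcripts across spots lay nearer to 0 at P60 than at P6. Fewer counts of the lists per spot at P60 were tested by thinning list and endothelial sums to the lowest mean of any section. The median ratio of the new to the old difference was 0.748, past the bound set beforehand against this as the whole cause. The 4 lists still differed with limma (adjusted p = 0.0209 for immature neuron, 0.00794 for cell division, 0.000981 for basement membrane and 0.000634 for ribosomal protein genes). With these sums, averaged over 20 draws, 11 of the 33 lists passed. The median was raised by the ratios of 1.04 for basement membrane and 0.886 for ribosomal protein genes. Basement membrane counts per spot at P60 (2.30 and 2.08 UMIs) lay within those at P6 (1.88 and 2.40), so that ratio was no test. Counts did fall for immature neuron and cell division genes, and their ratios were 0.593 and 0.609. Fewer counts could therefore account for part of the difference in these 2 lists. Differences between regions within a section are argued against as the whole cause for the immature neuron, cell division and basement membrane lists, whose median ratio after centring within clusters was 0.820; with differences in z of 0.0890 (SE 0.0180), -0.111 (SE 0.0239) and -0.0786 (SE 0.0186) before and 0.0671 (SE 0.0189), -0.0909 (SE 0.0199) and -0.0717 (SE 0.0256) after, their unadjusted p were 0.00926, 0.00258 and 0.0265 and none passed after adjustment over 33 lists. For the ribosomal protein list the ratio was 0.155, which is consistent with an association carried by differences between regions, and a biological change with age in where vessels lie relative to dividing cells and neurons is a hypothesis that was not tested.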
